A study of Drosophila melanogaster with 8 samples.

How the data were processed

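The series holds 8 poly(A) RNA sequencing libraries from GFP-positive hemocytes of larvae in the third instar, sorted by flow cytometry from animals carrying hmlΔ>2xeGFP. Per the labels, 5 larvae were bled per collection at 96 h after egg laying, 20000 cells were sorted per replicate, larvae were kept at 25 °C, libraries were amplified for 18 PCR cycles from a kit not described as strand-specific, and fragments were sequenced as paired ends of 150 nt in a pool of 20 libraries, of which 8 were analysed here. The labels give 1 batch for all libraries. They call the libraries of one diet replicates without saying whether these came from separate cultures or sorts, so the p-values measure the spread between these libraries, which may be partly technical.

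The deposited table gives whole-number counts of reads per gene, not normalized, for 11769 FlyBase gene identifiers. Per the submitters' processing notes, reads were trimmed with Trim Galore 0.6.7, aligned with STAR 2.7.10a to dm6 and counted with featureCounts, for which no version is given, and the strand setting and the treatment of multiply mapped reads are not given in the sources used here. Counts of near-identical copies such as the Hsp70 genes, of genes with overlapping exons and of antisense genes are therefore uncertain. Every column matched 1 sample and every row named a gene. The smallest total of any gene over the 8 libraries was 2 counts, held by 355 genes, so genes below that had been removed before deposit. No pair of libraries held identical values, and library pairs within a diet differed by more than counting noise (chi-square per degree of freedom from 7.75 to 129). Symbols, coordinates and exonic lengths came from the Ensembl 115 annotation of the same assembly and the gene name table given with it. A symbol was found for 11698 identifiers, and the 71 without one held 0.790% of all counts.

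Total counts per library ran from 20817891 to 24733521. Differential expression was tested on the deposited counts with edgeR 4.0.16 in R 4.3.3. Genes were kept by filterByExpr with its default minimum count of 10, which left 7844 genes with 99.957% of the counts. Libraries were scaled by TMM, a negative binomial model with diet as the only term was fitted with robust quasi-likelihood, and p-values were adjusted by Benjamini-Hochberg with a threshold of 0.05. The common biological coefficient of variation was 0.101. Standard errors are the log2 fold change divided by the square root of its F statistic. CPM values use the TMM-scaled library sizes and are given as mean ± SD over 4 libraries per diet; list sums over all members use the unscaled library sizes. Counting intervals are exact binomial intervals at 95% and cover counting error only, since PCR copies were not told apart by molecular identifiers.

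Before the data were examined, 44 gene lists were fixed, covering signalling, metabolic and immune pathways, hemocyte classes, other larval tissues and quality measures. The 38 lists with at least 5 tested members were compared with all other genes by camera (limma 3.58.1) at its preset inter-gene correlation of 0.01, with Benjamini-Hochberg adjustment over the lists. Each list's members were also counted as adjusted over all genes and as adjusted over the list alone. The genes to be named were set by a rule: among genes past the threshold with a mean of at least 2 CPM and no overlap between the diets, the 10 largest rises and 10 largest falls; the 5 smallest p-values per direction; dpp and the BMP list; the markers Hml, NimC1, lz, PPO1, atilla and Lsp2; and up to 4 members with the smallest p of each list described. The genes sug, Men, Hsp70Aa and Hsp70Bb were named after their values had been seen.

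The model was tested on simulated counts for the same 7844 genes with 200 genes changed. Of 50 genes changed at each size, the test recovered 26 at 1.25-fold, 43 at 1.5-fold, 46 at 2-fold and 48 at 4-fold, and 9 of 172 calls were false. All 3 simulated lists that had been shifted passed camera, and none of 27 unshifted lists did, although simulated genes vary independently of each other. The scarcest genes were given no change, far fewer genes changed than the 2040 called in the data, and no simulated library was made to stand apart. The recovery therefore does not speak for scarce genes or for data with a deviating library.

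Alternatives fixed before the data were examined were RLE, upper quartile and library-size scaling, no low-count filter, a stricter filter of at least 5 CPM in 4 libraries, DESeq2 1.42.0, limma-voom with quality weights, a replicate block, leaving out each library, camera with an estimated correlation, fry, a test against a 1.5-fold change, a threshold of 0.1, and an exact permutation test for dpp. Leaving out CD replicate 1 and HSD replicate 4 together, and a crystal cell covariate, were chosen after seeing the data. Base composition was not examined, since no genome sequence was used here.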

Results

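Gene expression was measured in larval macrophages of Drosophila melanogaster, the hemocytes that engulf debris and secrete much of the extracellular matrix, on a control diet (CD) or a high-sugar diet (HSD). The control food was a sucrose-yeast medium, and the high-sugar food was the same medium with a 10x sucrose supplement. Larvae in the third instar carried hmlΔ>2xeGFP, a reporter that marks hemocytes through the Hemolectin (Hml) promoter, and 20000 GFP-positive cells were sorted for each library at 96 h after egg laying. Each diet had 4 libraries, CD replicates 1, 3, 4 and 5 and HSD replicates 1, 2, 3 and 4. The summed gene counts ran from 20817891 in CD replicate 1 to 24733521 in CD replicate 3, and 7844 of the 11769 genes listed had enough counts to be tested. The title of the series concerns macrophage-derived Dpp and sterol hormone synthesis under dietary stress, so the first question was whether dpp transcripts differed between the diets.

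The transcript of dpp, which encodes the BMP2/4-type ligand Decapentaplegic, was 1.57-fold higher in the sorted GFP-positive cells of larvae on the high-sugar diet. Those cells were measured as a pool that also held markers of other hemocyte classes, so the rise cannot be assigned to macrophages alone. Mean abundance was 65.1 ± 3.21 CPM (counts scaled to library size) on the high-sugar diet and 41.5 ± 1.67 CPM on the control diet (SD, n = 4 each), and every HSD library lay above every CD library. The log2 fold change was 0.65 with a standard error of 0.0556 (edgeR quasi-likelihood test, adjusted p = 3.41e-06), and an exact permutation test on log2 CPM gave a two-sided p of 0.0286, the smallest that 4 libraries against 4 allow. The transcript of brk, a repressor of BMP target genes that Dpp signalling itself holds down, was lower, at 7.16 ± 1.30 CPM against 12.2 ± 1.18 CPM (log2 fold change −0.77, edgeR adjusted p = 0.00068). Whether this fall is linked to dpp was not tested, and the pathway's inhibitor gene Dad did not pass (log2 fold change 0.023, edgeR adjusted p = 0.896). The activin-type ligand gene mav was 1.32-fold higher at a low level, 5.06 ± 0.512 CPM against 3.85 ± 0.189 CPM (edgeR adjusted p = 0.031).

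The other measured members of the BMP and activin list did not pass the test. Of its 23 tested members, 2 rose, 1 fell and 20 did not pass, and adjusted over the list alone 1 rose and 1 fell. The second BMP ligand gene gbb stood at 84.9 ± 3.49 CPM on the high-sugar diet and 85.2 ± 6.25 CPM on the control diet, a log2 difference of −0.00 with a standard error of 0.0588. The receptor genes tkv, sax and put had log2 fold changes of −0.09, −0.02 and 0.06, the transducer gene Mad −0.17 and the inhibitor gene Dad 0.02. As a group the list did not stand apart from the remaining genes (camera adjusted p = 0.99, and adjusted p = 0.995 with an estimated correlation), and its median of −0.01 and mean of 0.01 differed in sign. The dpp gene lies on chromosome 2L from 2428372 to 2459823 and brk on X from 7307939 to 7311132 in the dm6 assembly.

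The dpp difference did not exceed 1.5-fold beyond its error (edgeR glmTreat adjusted p = 0.728), and the call ended when the mean of the crystal cell markers was added as a covariate (log2 fold change 0.52, standard error 0.167, edgeR adjusted p = 0.12; 4.12e-23 to 0.12 over the alternative fits). That covariate shares 89% of its variance with diet and raised standard errors by a median factor of 3.02. With library size as the only scaling 1 member of the list was called higher and 9 lower, tkv, sax, gbb and Mad among them, with a median of −0.18, and the mav call was lost (edgeR adjusted p = 0.133), as it was without CD replicate 3, 4 or 5 or HSD replicate 1 or 2 (edgeR adjusted p from 0.0523 to 0.0943), without a low-count filter (0.0537), with a replicate block (0.259) and with the covariate (0.998; over all alternatives 0.0066 to 0.998).

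**Figure D1:**
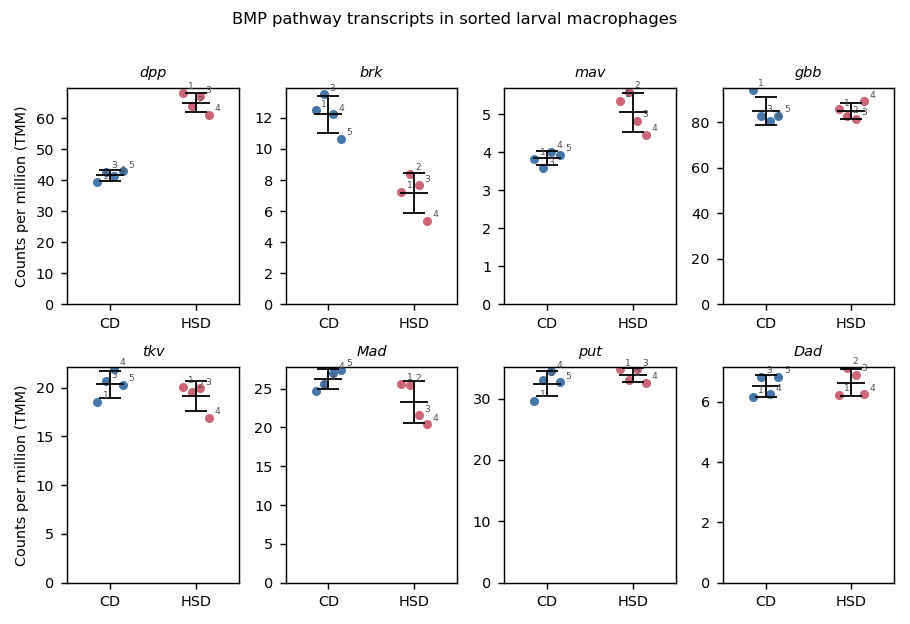
CPM (TMM-scaled) of 8 BMP pathway transcripts in each library, with replicate numbers beside the points; black bars give the mean and SD of the 4 libraries per diet. The 4 HSD values of dpp lie between 61.1 and 68.2 CPM and the 4 CD values between 39.3 and 42.9 CPM, while gbb, tkv, put and Dad overlap between the diets.

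Across the transcriptome 1128 genes were higher and 912 lower on the high-sugar diet, 26.0% of the genes tested. Most differences were small: 715 of the higher and 715 of the lower genes changed by less than 1.5-fold, while 200 rose and 108 fell by at least 2-fold. The smallest p-values among the rises belonged to Idgf1 and Idgf2, which encode secreted chitinase-like growth factors. Idgf1 rose 6.31-fold, from 44.0 ± 3.85 to 278 ± 21.9 CPM, and Idgf2 rose 4.17-fold, from 188 ± 13.5 to 783 ± 18.6 CPM (SD, n = 4 each, edgeR adjusted p = 5.92e-10 for both). They were followed by the aquaglyceroporin gene Eglp4 (2.32-fold), the abundant transcript FBgn0040813 (2.84-fold, to 4712 CPM), which has no symbol in the tables used, and the pyridoxal kinase gene Pdxk (2.34-fold). Among the falls the smallest p-values belonged to Papss, which makes the sulfate donor PAPS, the fascin gene sn, CG17124, the immunoglobulin-superfamily receptor gene Dscam1 and the intramembrane protease gene SppL. Their log2 fold changes ran from −1.70 for CG17124 to −0.76 for SppL.

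Among genes with a mean of at least 2 CPM and no overlap between the diets, the largest rises were in CG1208 (log2 fold change 5.64), atilla (29.1-fold), CG6733 (16.8-fold), TP53INP (10.9-fold), CG15740 (8.59-fold), CG17109 (8.47-fold) and Thor (8.004-fold), followed by CG34054, tbrd-1 and loh between 6.59-fold and 7.52-fold. CG1208 and atilla were close to absent on the control diet, with 17 and 19 counts summed over the 4 CD libraries, and the atilla log2 fold change of 4.87 became 6.60 without CD replicate 5. Thor, the translation repressor 4E-BP and a textbook target of FOXO, stood at 45.2 ± 6.74 CPM against 5.63 ± 1.73 CPM. The largest falls were in Obp99b (log2 fold change −3.16; the call was lost without CD replicate 1 and HSD replicate 4 together, edgeR adjusted p = 0.0723, and over all alternatives the adjusted p ran from 6.04e-06 to 0.345), the myo-inositol oxygenase gene Miox (−2.87), NT5E-2 (−2.56), blot (−2.44), CG6163 (−2.06), yin (−2.06), sro, Ama (−1.97), CG6287 (−1.91) and the fatty acid binding protein gene fabp (−1.86). In sro the mean was 1.43 CPM against 5.77 CPM. Miox was the most abundant of these on the control diet and fell from 264 ± 26.7 to 36.1 ± 9.22 CPM. The exons of fabp share 72.1% of their length with the gene sea on the same strand, so its count is uncertain. In 2193 genes, 28.0% of those tested, the libraries of the diets did not overlap, where chance gives 2.86%.

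With library size as the only scaling the median log2 fold change of all tested genes moved by −0.16 and the calls became 690 higher and 3161 lower. The share of higher calls was then 17.9% in place of 55.3%, so all directions here are relative to the TMM scale.

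**Figure D2:**
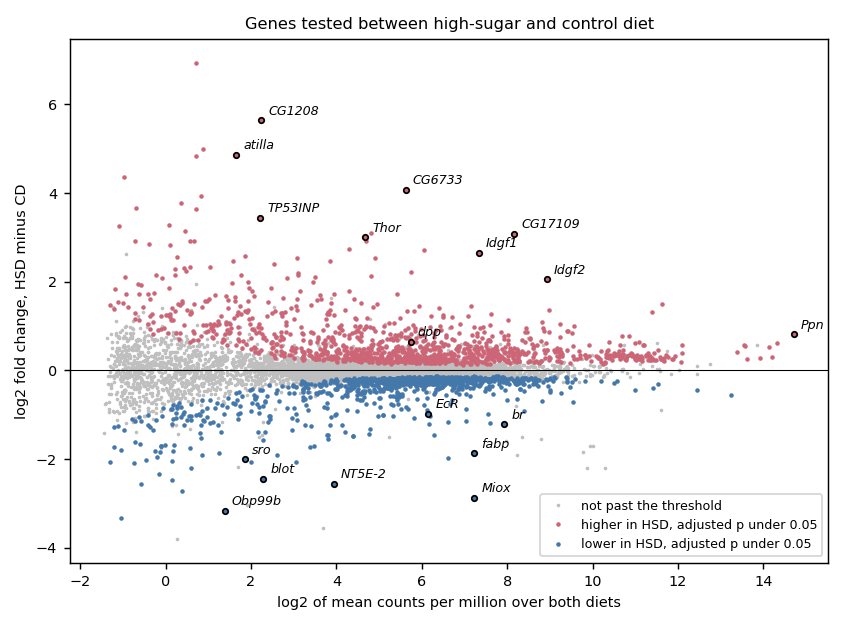
Log2 fold change between the diets (HSD minus CD) against the log2 of the mean CPM over both diets for the 7844 tested genes; red points were higher and blue points lower in HSD at an edgeR adjusted p under 0.05, grey points did not pass. Circled genes are named in the text, with CG1208 and atilla at the upper and Obp99b and Miox at the lower edge of the named genes.

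Markers of the 3 hemocyte classes were more often higher than lower on the high-sugar diet. In the plasmatocyte list, the markers of mature macrophages, 9 of 14 members rose and none fell, the same counts as when adjusted over the list alone. The matrix genes Ppn and SPARC rose by log2 fold changes of 0.82 and 0.58 and the scavenger receptor gene Sr-CI 1.38-fold, and Ppn was among the most abundant transcripts, at 34349 ± 2106 CPM against 19455 ± 1749 CPM. Hml itself, whose promoter drives the sorted reporter, stood at 20793 ± 1794 CPM against 16886 ± 1921 CPM (log2 fold change 0.30, edgeR adjusted p = 0.0256). The Hml call was lost without CD replicate 3 (edgeR adjusted p = 0.0555) and without HSD replicate 1, 2 or 3 (0.0737, 0.0626 and 0.0504), with library size as the only scaling (0.343), with a replicate block (0.231) and with the crystal marker covariate (0.924; over all alternatives 9.56e-05 to 0.924). The phagocytosis receptor gene NimC1 rose 1.17-fold (edgeR adjusted p = 0.0251), a call lost without HSD replicate 1, 2 or 3 (0.0645, 0.0749 and 0.0546) with library size as the only scaling (0.561), with a replicate block (0.168) and with the covariate (0.711; over all alternatives 0.00175 to 0.711). The list passed camera (adjusted p = 0.00021), and the adjusted p was 0.268 with an estimated correlation. Its counts became 6 higher and 1 lower with library size as the only scaling, and the median of 0.27 became 0.11. The summed muscle markers were also higher in every HSD library, at 101 to 124 CPM against 44.2 to 73.8 CPM, as were the lymph gland markers, at 1183 to 1300 CPM against 803 to 912 CPM.

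Of the 11 crystal cell markers, genes of the hemocytes that make prophenoloxidase for melanization, 10 rose and none fell, and adjusted over the list alone all 11 rose. The lineage transcription factor gene lz rose 1.55-fold, klu 1.81-fold, Naxd 1.56-fold and CG17109 8.47-fold, and the prophenoloxidase gene PPO1 rose 1.49-fold, from 9582 ± 719 to 14316 ± 2475 CPM (edgeR adjusted p = 0.00896, and 0.0715 with a replicate block). The camera adjusted p was 4.4e-06, and 0.435 with an estimated correlation. The libraries of one diet were not alike in these markers. On unscaled library sizes they summed to 30980 CPM in HSD replicate 4, inside the CD range of 26940 to 32200 CPM. In the other HSD libraries they summed to 43160 to 47060 CPM. On the TMM scale the mean log2 CPM of the markers was 8.884 in HSD replicate 4, above the CD libraries at 8.185 to 8.421. In the other HSD libraries that mean was 9.314 to 9.404. Without HSD replicate 4 and CD replicate 1 all 11 markers rose.

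Lamellocytes are large hemocytes seen after wasp infestation or wounding. Of 12 markers, 6 rose and 1 fell, also when adjusted over the list alone. The rises included atilla, the integrin gene ItgaPS5 (1.74-fold, from 188 ± 8.20 to 328 ± 10.8 CPM), mdu (5.02-fold) and ItgaPS4, which had 2 counts over all CD libraries and 279 over all HSD libraries, a ratio of 154 after division by the TMM-scaled library sizes, with an exact 95% counting interval of 42.4 to 1280. The list passed camera (adjusted p = 0.0287) but not without CD replicate 1 (0.163), without CD replicate 1 and HSD replicate 4 together (0.129), with limma-voom (0.0641) or with the stricter filter (0.326), where 3 of 9 tested members rose and the median of 0.51 became 0.10. Its adjusted p was 0.435 with an estimated correlation, and with library size as the only scaling 6 rose and 3 fell. On unscaled library sizes the summed abundance of these markers overlapped between the diets, at 2962 to 3336 CPM in HSD and 2914 to 3744 CPM in CD. On the TMM scale their mean log2 CPM was higher in every HSD library, at 6.084 to 6.397 against 4.989 to 5.284. That mean weighs scarce transcripts such as atilla and ItgaPS4 as much as abundant ones.

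**Figure D3:**
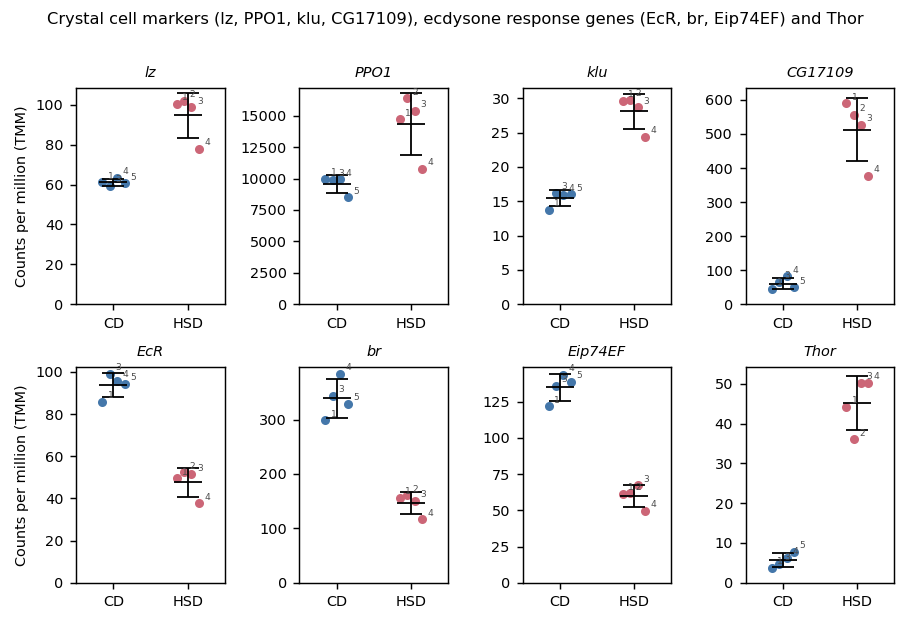
CPM (TMM-scaled) per library for 4 crystal cell markers, 3 ecdysone response genes and Thor, with replicate numbers beside the points and the mean and SD of 4 libraries per diet in black. HSD replicate 4 is the lowest HSD library for lz (77.8 CPM) and PPO1 (10754 CPM), yet above the CD libraries, and EcR, br and Eip74EF are lower in every HSD library than in every CD library.

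In the cytosolic ribosomal protein list 81 of 85 members rose and none fell (83 rose when adjusted over the list alone), by a median log2 fold change of 0.31, as in RpL15 (1.30-fold) and RpL22 (1.30-fold), whose exons share 34.3% of their length with a noncoding gene. Its camera adjusted p was 8.51e-21, and 0.522 with an estimated correlation. With library size as the only scaling 45 members rose and the median was 0.15. The mitochondrial ribosomal proteins had a median of −0.06, with 2 of 73 lower, and the nuclear-encoded oxidative phosphorylation subunits a median of 0.08, with 1 of 65 higher (none of either list when adjusted over the list alone). These 2 lists passed camera (adjusted p = 0.0403 and 0.0287) but not with an estimated correlation (adjusted p = 0.865 for both). The mitochondrial ribosomal call was lost without CD replicate 1 (0.7) and without HSD replicate 1, 2 or 3 (0.277, 0.0733 and 0.0684), and the oxidative phosphorylation call without CD replicate 3, 4 or 5 (0.131, 0.168 and 0.0608) or HSD replicate 4 (0.319). Without CD replicate 1, 18 oxidative phosphorylation genes rose, without HSD replicate 4, 6 mitochondrial ribosomal genes fell, and with library size as the only scaling 46 mitochondrial ribosomal genes were lower, with a median of −0.22, and 10 oxidative phosphorylation genes, with a median of −0.09. The mitochondrial ribosomal call was also lost with upper quartile scaling (0.0566) and limma-voom (0.157), and the oxidative phosphorylation call with library size as the only scaling (0.824), without a filter (0.0715) and with a replicate block (0.0517).

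Of 14 glycolysis genes 7 fell and 1 rose, and adjusted over the list alone 8 fell and 2 rose. The triose phosphate isomerase gene Tpi fell by 0.82 on the log2 scale, the phosphofructokinase gene Pfk by 0.52 and the hexokinase gene Hex-A by 0.30, while Gpdh1, whose enzyme draws triose phosphate towards glycerol, rose 1.36-fold. The camera adjusted p was 0.0287, 0.0612 with library size as the only scaling, 0.0514 with a replicate block, and 0.268 with an estimated correlation. Of 13 genes of sugar transport and glycogen or trehalose metabolism 8 rose and 3 fell, or 8 and 4 adjusted over the list alone. The trehalose transporter gene Tret1-1 rose 3.91-fold and the sorbitol dehydrogenase gene Sodh2 1.88-fold, whereas glycogen synthase (Glys) fell by 0.67 and the debranching enzyme gene CG9485 by 1.03 on the log2 scale. This list did not pass camera (adjusted p = 0.186), and with library size as the only scaling 7 rose and 5 fell. Exons of Sodh2 and CG9485 share 56.8% and 30.2% of their length with genes on the opposite strand, whose reads could not be told apart.

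Of 25 lipogenesis and lipid storage genes 8 rose and none fell, also when adjusted over the list alone. The diacylglycerol acyltransferase gene mdy rose 1.94-fold, the desaturase gene Desat1 1.28-fold and SREBP, the regulator of fatty acid synthesis, 1.28-fold, but the carnitine palmitoyltransferase gene whd, which acts in fatty acid breakdown, also rose 1.66-fold. The camera adjusted p was 0.0138, and 0.268 with an estimated correlation. With library size as the only scaling the list's median was −0.03, with 7 members higher and 4 lower. In the insulin and TOR list 9 of 23 members rose and 2 fell, also when adjusted over the list alone, without the list passing camera (adjusted p = 0.102), and with library size as the only scaling 5 rose, 5 fell and the median of 0.07 became −0.09. Besides Thor, the amino acid transporter gene path rose 1.78-fold, REPTOR-BP, whose product is a partner of the transcription factor REPTOR that TOR holds inactive, 1.747-fold, and Pdk1, a kinase that activates Akt, 1.41-fold.

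Of 19 genes in the list of secreted signals, which also holds some of their receptors, 12 rose and 1 fell, also when adjusted over the list alone. Beside Idgf1 and Idgf2, Idgf3 rose 2.05-fold, and egr, the fly tumour necrosis factor, rose 1.63-fold. The camera adjusted p was 0.000103, and 0.268 with an estimated correlation, and with library size as the only scaling 10 members rose and 2 fell. Of 17 extracellular matrix genes 11 rose and 3 fell, also when adjusted over the list alone. Glt rose 1.34-fold, and the integrin gene mew fell by 1.54 on the log2 scale. The matrix list passed camera (adjusted p = 0.0187) but not without CD replicate 1 (0.0628), and its adjusted p was 0.435 with an estimated correlation. Among the matrix genes 7 rose and 4 fell with library size as the only scaling.

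Of 21 phagocytosis and Nimrod genes 10 rose and 2 fell, and 11 and 3 adjusted over the list alone. NimB4, NimB5 and the thioester protein gene Tep4 rose 1.70-fold, 1.67-fold and 1.79-fold, and Dscam1 fell by 1.40 on the log2 scale (camera adjusted p = 0.0138, and 0.276 with an estimated correlation). Among the phagocytosis genes 7 rose and 4 fell with library size as the only scaling. Of 26 lysosome and autophagy genes 9 rose and none fell, with 10 rising adjusted over the list alone, among them the protease genes CtsL1 and cathD (1.49-fold and 1.48-fold) and Hexo1 (1.39-fold). The camera adjusted p of the lysosome list was 0.0138, 0.0606 with library size as the only scaling, where 3 rose, 7 fell and the median was −0.03, and 0.268 with an estimated correlation. The lipoprotein and scavenger receptor list went both ways, with 7 of 17 members higher and 3 lower, also when adjusted over the list alone (camera adjusted p = 0.44), and its median of 0.03 and mean of −0.01 differed in sign. Its lipoprotein receptor gene LpR2 rose 1.68-fold and Sr-CIV 1.76-fold.

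Among 28 Toll and IMD pathway components 9 rose and 4 fell, and 11 and 4 adjusted over the list alone, without the list passing camera (adjusted p = 0.0619). The serine protease gene modSP rose 2.25-fold, the Toll ligand gene spz 1.47-fold and IKKbeta 1.58-fold, while dl, a transcription factor of the Toll pathway, fell by 0.61 on the log2 scale. Without CD replicate 3 or 5 or HSD replicate 1, 2 or 4, 2 of the components were lower in place of 4, and with library size as the only scaling 6 were higher, 9 lower and the median was −0.03. Of 7 tested antimicrobial peptide genes 2 rose (3 adjusted over the list alone) and none fell (camera adjusted p = 0.091). That count rested on single libraries: 4 rose without CD replicate 5 and 3 without HSD replicate 2, 1 without CD replicate 1, and 0 without CD replicate 3 or 4 or HSD replicate 1, 3 or 4.

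Ecdysone response genes and cell cycle genes were more often lower than higher. Of 18 ecdysone response genes 7 fell and 2 rose, or 7 and 3 adjusted over the list alone. The early response genes br and Eip74EF fell from 339 ± 35.4 to 146 ± 19.98 CPM and from 135 ± 9.42 to 60.0 ± 7.41 CPM, and the receptor gene EcR from 93.7 ± 5.70 to 47.7 ± 6.85 CPM (edgeR adjusted p = 1.07e-05, 1.28e-06 and 1.16e-05), while Eip63E rose 1.39-fold. The list did not pass camera (adjusted p = 0.0559), but it passed fry as lower (adjusted p = 0.0204). In the ecdysteroid biosynthesis list only 3 genes had enough counts to be tested, of which sro (shroud) and shd (shade) fell, to 1.43 ± 0.141 and 0.904 ± 0.495 CPM from 5.77 ± 2.39 and 2.62 ± 0.538 CPM. Of 35 cell cycle and DNA replication genes 12 fell and none rose, and 16 fell adjusted over the list alone. Those with the smallest p-values had log2 fold changes of −0.30 (fzy and borr), −0.28 (Top2) and −0.26 (feo), and the lowest value in the list was −0.43. The camera adjusted p was 0.000265, and 0.404 with an estimated correlation. Without CD replicate 3 or 4, 7 cell cycle genes fell, and with library size as the only scaling 31 did.

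**Figure D4:**
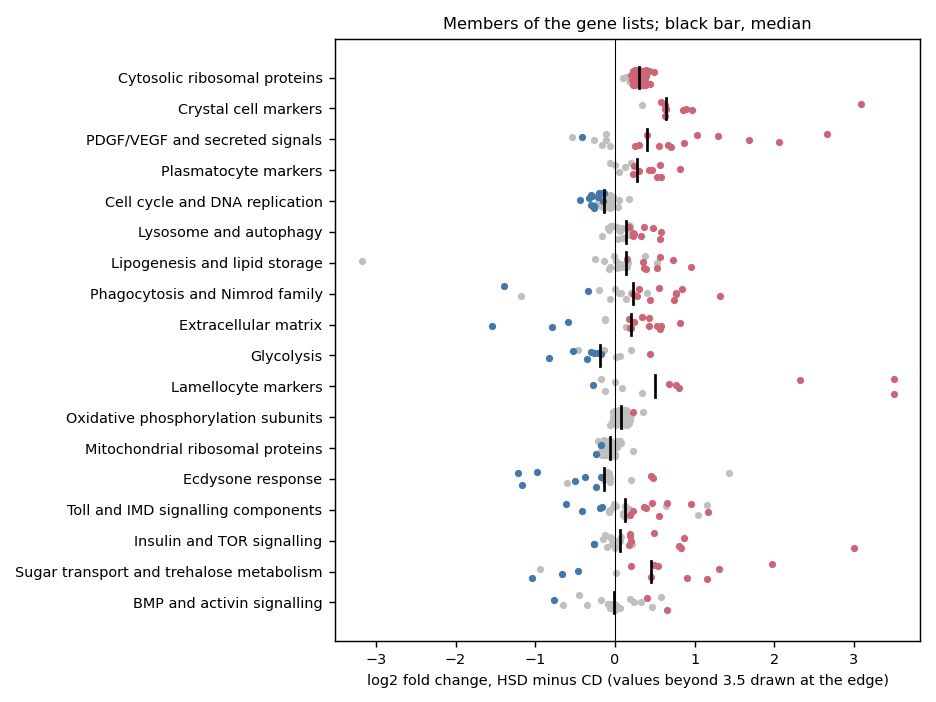
Log2 fold change (HSD minus CD) of every tested member of 18 gene lists; red points were higher and blue points lower in HSD at an edgeR adjusted p under 0.05, grey points did not pass, and the black bar is the list's median. The ribosomal proteins form a narrow cluster with a median of 0.31, whereas the BMP list is centred on −0.01.

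In all, 13 of the 38 lists with at least 5 tested members passed camera at its preset correlation, 10 higher and 3 lower, none passed with the correlation estimated from these libraries, and 19 passed the rotation test fry, which asks only whether a list's genes moved on balance. Some lists that missed camera passed fry as higher. They included the Toll and IMD (fry adjusted p = 0.0127), insulin and TOR (0.0404), sugar transport (0.00558) and lipoprotein receptor lists (0.00869). With the crystal marker covariate 4 of the 13 lists kept their call and direction, those of cytosolic ribosomal proteins, secreted signals, cell cycle and oxidative phosphorylation. Camera then gave an adjusted p of 0.0969 for the plasmatocyte, 0.312 for the lamellocyte, 0.439 for the glycolysis, 0.417 for the lipogenesis, 0.483 for the phagocytosis, 0.288 for the lysosome and 0.286 for the matrix list, and the crystal cell list, whose own mean is the covariate (0.445), and the mitochondrial ribosomal list (0.0396) changed direction. In 14 lists the mean over members separated the 4 HSD from the 4 CD libraries completely.

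The libraries grouped by diet. The first principal component held 54.1% of the variance and separated the diets, and the second held 17.1% and set CD replicate 1 apart from the rest. Pearson correlations of log2 CPM ran from 0.985 to 0.996 within a diet and from 0.974 to 0.983 between diets. CD replicate 1 carried 5.41% of its counts in heat shock protein genes, against 1.36% to 1.44% in the other CD libraries and 1.21% to 1.32% in the HSD libraries. No heat shock gene of the 16 tested passed in edgeR with all 8 libraries (1 at an unadjusted p under 0.05; 1 was lower in DESeq2 and 1 in limma-voom). Without CD replicate 1, 6 were higher and 1 lower in HSD, and with library size as the only scaling 4 were lower. The 10 most abundant genes took 13.5% to 15.03% of the counts in CD and 16.5% to 19.04% in HSD libraries. Markers of lymph gland progenitors and niche, the larval blood-forming organ, summed to 1183 to 1300 CPM in the HSD libraries and to 803 to 912 CPM in the CD libraries. Of 4 tested, 2 rose and none fell, also when adjusted over the list alone, and most of the sum was Tep4, which the phagocytosis list also holds, at 938 ± 38.3 CPM against 523 ± 46.6 CPM. Muscle markers also separated the diets: they summed to 101 to 124 CPM in the HSD libraries and to 44.2 to 73.8 CPM in the CD libraries. Of 16 tested muscle markers 3 rose and none fell (2 rose adjusted over the list alone), and 1 rose without CD replicate 5 or HSD replicate 1. The muscle list passed fry (adjusted p = 0.0404) but not camera (adjusted p = 0.139). On unscaled library sizes the sums of nephrocyte, midgut, fat body, neuron, germline and epidermis markers overlapped between the diets: nephrocyte and Malpighian tubule markers ran from 396 to 601 CPM, midgut markers from 459 to 532 CPM, fat body markers from 312 to 379 CPM, neuron and glia markers from 118 to 136 CPM, germline markers from 25.03 to 29.01 CPM and epidermis markers from 2.87 to 12.3 CPM. The TMM factors were 1.0148 to 1.0833 in CD and 0.9342 to 0.9569 in HSD libraries. Divided by them, the midgut and germline sums were higher in every HSD library than in every CD library. The mean log2 CPM over the tested members, on the TMM scale, overlapped between the diets in those of these lists with at least 5 tested members. Single members did pass: 2 of 6 midgut and 2 of 10 fat body markers rose and none fell. Of 7 nephrocyte and Malpighian tubule markers 1 rose and 2 fell, and of 4 neuron and glia markers 1 rose and 1 fell. No tested germline or epidermis marker passed. Salivary gland markers summed to 2.701 to 3.55 CPM in HSD and 4.29 to 9.37 CPM in CD, and the fat body gene Lsp2 had 1 to 38 counts per library.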

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

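The scaling and crystal cell share tests in this part, and the reading of the developmental stage, were chosen only after the results were seen. The length tests and the test without CD replicate 1 were written before they were run, but not necessarily before the results were seen. The ecdysone response genes in the length test were taken from the calls, so that test was framed after the calls were known. Leaving out each library had been fixed before the data were examined.

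A library stood apart from the other 3 of its diet in 38 of 300 comparisons. About 1 in 20, or 15, would be flagged by chance among independent items chosen without regard to their values. That did not hold: sug, Men, Hsp70Aa and Hsp70Bb were named after their values had been seen, and each was flagged. The heat shock share, the heat shock list and the Hsp70 genes also share transcripts. The count of 38 therefore cannot be weighed against 15. CD replicate 1 accounted for 21 of the 38 flagged comparisons. The ratio of the gap to the whole range is given for each and exceeded the 95% critical value of Dixon's test.

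CD replicate 1 was high in the heat shock share of counts (5.41%, ratio 0.98), the mean of the heat shock list (ratio 0.948), Hsp70Aa (5095 CPM against 239 to 354, ratio 0.976) and Hsp70Bb (ratio 0.962). It was also high in sug (115.5 CPM against 11.2 to 22.7, ratio 0.89), Npc2h (0.986), blot (0.965), Ama (0.909), RpL15 (0.907), sn (0.903), sro (0.885), Idgf2 (0.885), Cat (0.876), CG6287 (0.868), Tpi (0.853) and the mean of the mitochondrial ribosomal list (0.864). It was low in CG15740 (0.897), klu (0.865), NimC1 (175 CPM against 213 to 219, ratio 0.851), CG6163 (0.836) and the mean of the BMP list (0.863). CD replicate 5 was high in Hexo1 (0.965), atilla (0.851) and whd (0.844) and low in PPO1 (0.96) and Men (0.882). CD replicate 4 was low in Glt (0.886), and it held the only 2 CD counts of ItgaPS4 (ratio 1). HSD replicate 1 was high in Ppn (0.916), the insulin and TOR list (0.963) and the lysosome list (0.851) and low in ND-B12 (0.841). HSD replicate 3 was low in Idgf2 (0.957) and in the mitochondrial share of counts (1.40% against 2.65% to 2.79%, ratio 0.897). HSD replicate 4 was low in lz (0.861), Traf4 (0.885) and tkv (0.84) and high in the endoplasmic reticulum stress list (0.9).

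The first pattern weighed was the rise of crystal cell markers. Library scaling did not account for it, since with library size alone the mean of the 11 markers was still 0.73 higher on the log2 scale in HSD (standard error 0.129). A larger share of crystal cells among the sorted cells stays open for the 10 markers other than CG17109: within the diets they deviated together, with a median pairwise correlation of 0.76 where 95% of random lists of like abundance gave −0.332 to 0.489. Markers regulated together inside the cells would also correlate. CG17109, at a log2 fold change of 3.08, lay above the range of 0.34 to 0.97 of the others, so a share that accounts for those may not account for it.

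The second pattern was the rise of the cytosolic ribosomal protein genes. With library size as the only scaling the mean of the list was still 0.142 higher (standard error 0.0481), and without CD replicate 1 it was 0.356 higher (standard error 0.0421), which argues against scaling or that library as the whole cause. Gene length and abundance could account for part of it: the list's median of 0.3082 lay above 95% of random lists matched on both, 0.118 to 0.274, but those lists had themselves a median of 0.168. The matching was incomplete, since the matched genes had a median log2 CPM of 8.68 and the list 10.8. A response of ribosomal protein transcripts to the diet stays open as a hypothesis.

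The third pattern was the fall of 7 ecdysone response genes, EcR, br and Eip74EF among them. After removal of each library's trend with exonic length and abundance, their mean was −0.65 on the log2 scale (standard error 0.0448, against −0.665 before). Removing the trend thus changed the mean of these 7 genes little. The 7 genes had been picked because they were called lower in the same libraries, so a mean below 0 was close to set in advance. The whole list was not corrected in this way, so the test cannot decide whether length or abundance bears on the list. An earlier developmental stage of the HSD larvae at the same hour cannot be told apart from an effect of diet on these cells, because the labels give the hour and no stage within the instar. The list as a whole did not pass camera (adjusted p = 0.0559) but passed fry as lower (adjusted p = 0.0204), and neither result separates stage from diet.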

How the results depend on the processing

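Leaving out CD replicate 1 and HSD replicate 4 together, and the crystal marker covariate, were chosen only after the results were seen; the other alternatives were fixed before. dpp was higher on the high-sugar diet under every alternative run, and past the threshold in all but the test against 1.5-fold (edgeR glmTreat adjusted p = 0.728) and the covariate fit, where its log2 fold change was 0.52 (edgeR adjusted p = 0.12; 4.12e-23 to 0.12 over the fits). That covariate correlates with diet at 0.943 and raised standard errors by a median factor of 3.02, so the call ended mainly through the error, from 0.0556 to 0.167. Leaving out each library kept dpp between 0.62 and 0.68 and gave 1589 to 2631 changed genes, 929 to 1408 higher and 660 to 1223 lower, and 11 to 15 lists. RLE, upper quartile, no filter, the stricter filter and DESeq2 gave 1814 to 2215 changed genes, and leaving out both doubted libraries gave 2707.

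With library size only, 3851 genes changed, 690 higher and 3161 lower; 1601 of the 2040 genes were called again in the same direction, and the estimates of 17 had the opposite sign. Limma-voom called 2932 genes, 1502 higher and 1430 lower, and a threshold of 0.1 gave 2635 genes. The replicate block, fitted on the 3 numbers the diets share, gave 835 genes, 587 higher and 248 lower, and ended the calls of the glycolysis (0.0514) and oxidative phosphorylation lists (0.0517); it holds fewer libraries, and the numbers did not pair them (deviations correlated at −0.131, −0.0738 and −0.176, and 0 of 6 libraries correlated best with its own number). The test against 1.5-fold gave 271 genes, as it asks for more. The covariate gave 278 genes, 211 higher and 67 lower, and 49 of 141 named genes. The estimates of 129 of the 2040 genes had the opposite sign, and 8 lists passed, 5 of them among the 13, of which 4 kept their direction, while the glycolysis, lipogenesis, phagocytosis, lysosome, matrix, plasmatocyte, crystal cell and lamellocyte lists lost their calls. With it Pgd (−0.0366), yin (0.17), LManI (−0.0582), Zw (0.13), PPO1 (−0.45), Ncc69 (−0.17), Hml (−0.0589) and Mlp84B (−0.0589) reversed, as did the crystal cell (camera adjusted p = 0.445) and mitochondrial ribosomal lists (0.0396). With an estimated correlation 0 lists passed; camera was not run for DESeq2. Hsp70Aa ran from −2.05 to 0.60 over the left-out libraries, reversing without CD replicate 1. The first principal component held 35.99% without a filter, 64.42% with the stricter one, 57.73% in the block, 64.99% without both doubted libraries, and 51.12% to 59.97% with each library left out. Except where said, the cause was not tested. Depth limits genes near the filter, such as CG1208 and atilla with 17 and 19 CD counts.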

Other observations

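The reading of sug and Men was chosen after their values were seen, and the test of neighbouring genes and the tests of other splits were written before.

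Several lists that the comparison above did not describe held strong single changes. In the oxidative stress and glutathione list 6 of 32 members rose and 5 fell (6 and 6 adjusted over the list alone): the thioredoxin gene Trx2 rose 1.81-fold and the peroxiredoxin gene Prx2 1.37-fold, while the catalase gene Cat fell by 0.30 on the log2 scale, and without CD replicate 1, 12 members rose. The citrate synthase gene kdn rose by 0.58 on the log2 scale, as 1 of 2 rises among 20 citric acid cycle genes, a list whose median of −0.02 and mean of 0.03 differed in sign. Diap1, which restrains caspases, rose 1.47-fold, and the Notch target gene E(spl)m3-HLH rose 1.93-fold, as did Npc2h of the sterol trafficking list, 2.54-fold from 3.35 ± 0.419 to 8.51 ± 1.71 CPM (SD, n = 4 each). In the JNK list scaf rose 2.95-fold and Traf4, 26.8% of whose exonic length is shared with a noncoding gene, fell by 1.13 on the log2 scale. None of these 6 lists passed camera (adjusted p from 0.499 to 0.904), and with library size as the only scaling the medians of all 6 were negative, from −0.18 to −0.09. The sterol trafficking and JNK lists passed fry (adjusted p = 0.000693 and 0.0404), and the others did not (0.0568 to 0.363). The mean log2 CPM of the sterol trafficking list was 5.251 to 5.32 in HSD and 5.094 to 5.169 in CD libraries, with 1 of its 11 tested members called higher. The 5 falls in the oxidative stress list became 3 without CD replicate 4 or HSD replicate 3, 2 without CD replicate 5 or HSD replicate 1, and 1 without HSD replicate 2.

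The malic enzyme gene Men rose 2.48-fold, from 1546 ± 125 to 3838 ± 758 CPM (edgeR adjusted p = 0.000206). The gene sug, which encodes the sugar-responsive factor Sugarbabe, had 45.8 to 73.0 CPM in the HSD libraries and 11.2 to 22.7 CPM in CD replicates 3, 4 and 5, but 115.5 CPM in CD replicate 1. With all 8 libraries its log2 fold change was 0.53 (edgeR adjusted p = 0.682), and without CD replicate 1 it was 1.88 (edgeR adjusted p = 0.00561). Over all alternatives the adjusted p ran from 0.000777, with limma-voom quality weights, to 0.962.

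Changed genes lay beside each other on the chromosomes more often than shuffled calls did. Of 6259 pairs of adjacent tested genes whose spans do not overlap, 295 were called in the same direction, 182 both higher and 113 both lower, where 95% of 10000 shuffles gave 189 to 241 (one-sided permutation p = 1e-04, the smallest these shuffles can give). Without the 122 pairs whose symbols share a stem, as tandem gene families do, 272 pairs remained against 186 to 236 in the shuffles. The pair with the largest changes was CG17109 and CG6733, from 23095690 to 23099191 on 3R, with log2 fold changes of 3.08 and 4.07, and Idgf1, Idgf2 and Idgf3 follow each other from 16445278 to 16455194 on 2L. This is consistent with the hypothesis that neighbouring genes share regulation under the diet, but reads shared between copies and neighbours expressed in the same cell class were not separated from it.

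Of the 35 splits of the 8 libraries into 4 and 4, the real one gave 2040 changed genes and the highest of the others gave 1. Every other split put libraries of both diets on each side, so the diet difference widened the spread within its groups. Few calls could be reached there, so the splits cannot decide how many genes chance alone would give. For the number of gene lists chance was not excluded, and the splits cannot decide it. The real split gave 13 lists past camera at its preset correlation, and the highest other split gave 16. As many lists were given by 4 of the 35 splits, the real one included. The others among these each joined CD replicate 1 and further CD libraries with 1 HSD library, so they kept part of the diet difference. The counts of list members that passed the gene-wise test were made without the preset correlation, but members of a list can vary together. The correlation estimated from these libraries was 0.827 for the cytosolic ribosomal and 0.663 for the crystal cell list. Such counts are therefore not counts of independent genes.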
